A study of Neurospora discreta with 48 samples.

How the data were processed

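RNA from mycelial pads, labelled as mycelia and conidia, of 4 strains of Neurospora discreta at 4 times of a light and dark cycle was sequenced by the authors with 3 replicates per strain and time. Per the submitters' processing notes, the tools were FastQC 0.11.4, cutadapt 1.3, TopHat2 2.1.1, HTSeq, SAMtools, edgeR and DESeq, listed without role or order. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so coordinates are printed as the authors' deposited table gives them, as scaffold, start and end.

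The values come from 1 comparison table made by the authors, with 9280 genes on 64 scaffolds. Per the file headers, the DESeq columns hold a mean signal over both arms, a mean for each arm, a fold ratio, a log2 fold change, a p-value and an adjusted p-value. The arm means are counts divided by size factors and averaged over the libraries, as the deposited values show at their low end. Per the file headers, the edgeR columns hold a log2 fold change, an average log2 CPM, a likelihood ratio score, a p-value and a false discovery rate. The p-values that the authors deposited are rounded to 4 decimals. The deposited log2 fold change of DESeq held a spreadsheet error in 107 cells, all with a B mean of 0, and Inf in 46 cells with an A mean of 0, so log2 fold changes were computed from the arm means as B over A. Adjusting the deposited p-values over all 9280 rows by the Benjamini-Hochberg method gave the deposited adjusted values to within 0.0008 for DESeq, per the file headers, and 0.0006 for edgeR. Where edgeR p-values were deposited as 0, they were computed from the likelihood ratio in the authors' deposited table with 1 degree of freedom.

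The design fixed before the data were examined foresaw edgeR on counts, and fell back on the authors' deposited statistics if the table held those only, which was the case. Calls are therefore genes with a DESeq adjusted p under 0.05 in the authors' deposited table, the edgeR columns serve as the alternative, and no count model was fitted here. The rule for named genes took the 10 largest fold changes in each direction among called genes with a mean of at least 50 normalized counts, of which 2 per direction are printed because the IDs are not paired with names. In that ranking, genes at 0 in 1 arm came first, ordered by the edgeR log2 fold change in the authors' deposited table. The 22 gene lists fixed before the data were examined, among them clock, photoreceptor, conidiation and mating type genes and markers of conidia and sexual tissue, matched 0 entries of the table, so no list was tested.

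Low arm means carry the worth of 1 count in each library. Means under 3 were decomposed into whole multiples of 3 values per arm, with a tolerance of 0.0004, and all 425 such means of A and all 501 of B had exactly 1 decomposition. The size factors found ranged from 1.04 to 1.11 in A and from 0.866 to 1.15 in B. A fold against an arm listed at 0 is a lower bound against 3 counts over that arm, a mean of 0.961 in A and 1.15 in B. As an alternative chosen after the data had been seen, the floor was also set at 3 counts before the rescaling that missing whole numbers in the low counts would imply, a mean of 1.602 in A. Intervals for ratios with 1 to 3 counts are exact Poisson intervals at 95% for the low arm alone. They take every count of that arm at the average worth of the counts seen. Intervals and floors cover counting error only.

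Neighbouring calls were tested by shuffling the calls over the genes 10000 times, and runs of calls by 1000 shuffles. Scaffolds with at least 40 genes were tested with Fisher's exact test and with all 9280 rotations of the calls along the gene order, with Benjamini-Hochberg adjustment over scaffolds. These tests were chosen after the data had been seen. Positions of other libraries between the arms were compared for pairs of genes with 10000 permutations within each direction. On simulated data for the comparison of the parents with 9280 genes, 2 of 40 random call sets had a neighbour p under 0.05. Of the planted runs of 4 genes, 40 of 40 were found, which was fixed in advance because all 4 genes were set as called. That check covers the search for runs only and does not show how many real runs missed calls would hide. Fisher's exact test called no scaffold in 20 random sets. Those sets placed calls independently, so they do not vouch for that test where calls lie side by side. For low means drawn with 1 library rescaled by 1.6, the decomposition gave a factor from 1.5 to 1.749, and no library lacked a number without rescaling. Positions drawn in blocks for 486 genes gave a Spearman rho of 0.510 and independent positions a rho of -0.0043.

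Alternatives were the edgeR columns of the authors' deposited table, both tools together, an adjusted p under 0.01, a mean of at least 10 CPM, a 4-fold limit, other detection limits and, chosen after the data had been seen, leaving out overlapping gene models, equal arm totals, shuffles within scaffolds and rotations. In the table, 513 genes lie in overlapping pairs of models, whose reads may be shared. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.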

Results

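RNA from mycelial pads of the filamentous ascomycete Neurospora discreta, labelled as mycelia and conidia, was sequenced in 48 libraries, made of 4 strains at 4 times with 3 replicates of each. The strains were an African isolate (FGSC8831), a North American isolate (FGSC8578) and 2 progeny of these parents (N309-89 and N309-50). FGSC8831 and N309-89 carry the label high RI and the other 2 strains the label low RI, a term that the labels do not expand. Cultures grew at 25 °C under 12 h of light and 12 h of dark and were sampled after 15 min, 1 h or 2 h of light or in the 2 h dark sample. The study sought genes behind differences in the circadian clock between strains from different habitats.

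The comparison described here is that of the 2 parents at 15 min of light, with 3 libraries per strain. The other 42 libraries are not analysed here. Results are taken from the authors' deposited table, which gives 1 mean per gene for each of 2 arms called A and B. Its columns do not say which strain is which arm, so directions are given as A and B. The order of the strains in the table's name would make A the North American FGSC8578 and B the African FGSC8831. The arm means of the 9280 genes in the authors' deposited table summed to 9331506 normalized counts in A and 10507386 in B. The depth of the single libraries is unknown, and values are printed without an SD because the authors' deposited table holds no value per library. The labels do not say whether the 3 replicates came from separate cultures, so the p-values may measure technical spread only.

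In the comparison of the parents, 1388 of the 9280 genes (15.0%) differed at a DESeq adjusted p under 0.05 in the authors' deposited table, 643 of them higher in B and 745 higher in A. All but 1 of the 1388 genes differed by at least 2-fold. At 4-fold or more there were 234 genes higher in B and 425 higher in A, and at 16-fold or more 62 and 149. Of the called genes, 17 were listed at 0 in A and 43 at 0 in B; with these set at their lower bounds, the counts at 16-fold became 55 and 124 and those at 4-fold were 234 and 425. The 1388 calls became 891 at an adjusted p under 0.01 and 909 among genes with a mean of at least 10 CPM, and in the latter set 54.6% were higher in B, against 46.3% of the 1388. The median absolute log2 fold change in the authors' deposited table was 1.69 for genes higher in B and 2.25 for those higher in A. With genes at 0 in an arm set at their bounds, the medians were 1.69 and 2.23. The genes higher in A had a median level of 125 normalized counts over both arms, against 428 for those higher in B. Whether the larger folds in A follow from this lower level was not tested.

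**Figure D1:**
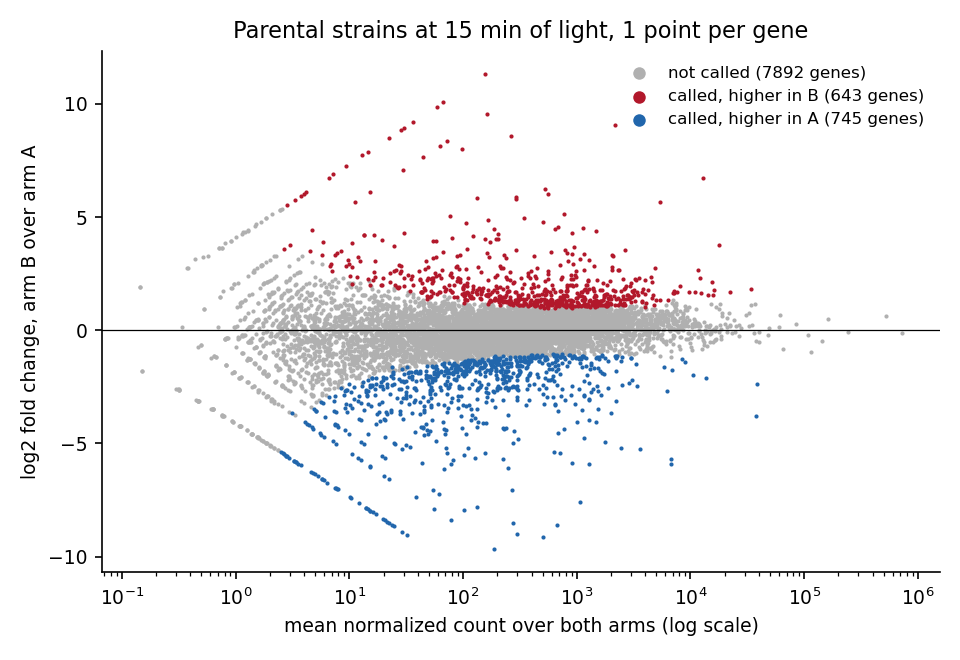
Log2 fold change of arm B over arm A (y axis, edgeR column of the authors' deposited table) against the mean normalized count over both arms (x axis, log scale), with 1 point per gene. Red points are the 643 genes called higher in B by the DESeq adjusted p, blue points the 745 called higher in A and grey points the genes not called by it. The straight lines of points at the left edge are genes with few or no counts in 1 arm, whose plotted values are fitted by the tool and are no bounds.

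The 2 named genes in each direction had a mean under 2 normalized counts in 1 arm. The authors' deposited table pairs no gene ID with a name or function, so genes are given by ID and position, at most 2 IDs per direction. On scaffold 13, the 222 bp gene model scaffold_13-snap.5.1 (protein 19484, positions 9865 to 10086) was listed at 0 in A and at 313 normalized counts in B in the authors' deposited table, at least 326-fold higher in B. The gene estExt_Genewise1Plus.C_20877 (protein 91759, scaffold 2, 1676759 to 1678140) was listed at 0 in A and at 134 in B in the authors' deposited table, at least 139-fold higher in B. Both bounds set arm A at 3 counts summed over its libraries, a mean of 0.961, and cover counting error only. A listed 0 does not tell a silent gene from one absent or diverged in that strain, which would also give no counts. That was not tested. In 1 library of A the low counts lacked the numbers 1 and 4, as counts multiplied by 1.5 to 1.749 and rounded would. With the floor at 3 counts before such a rescaling, a mean of 1.602, the bounds would fall to 196-fold and 83.7-fold. In the other direction, estExt_Genewise1.C_760003 (protein 88238, scaffold 76, 9951 to 11558) had a mean of 371 in A and 0.291 in B in the authors' deposited table. The B value is that of 1 count in 1 library. The ratio of 1276 has a 95% counting interval from 229 to 50413. Its lower end would be 176 if that library was rescaled as its missing count of 2 would imply. The interval takes every count in B at 0.291. A count in the other libraries of B was worth 0.375 or 0.385, so both lower ends may be too high. The gene e_gw1.6.909.1 (protein 60627, scaffold 6, 8027 to 9405) stood at 1010 in A and 1.55 in B in the authors' deposited table, 653-fold lower in B. For these 4 genes the authors' deposited table lists the adjusted p of both DESeq and edgeR at 0 to 4 decimals. Computed from the edgeR likelihood ratios in the authors' deposited table, the adjusted p was 2.8e-14, 3.36e-30, 6.61e-47 and 1.08e-48, in the order named.

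Among the 119 genes with a mean of at least 10000 normalized counts, 12 were called higher in B and 4 higher in A. A gene on scaffold 4 (792518 to 793694) rose from 236 in A to 25494 in B, 108-fold, with an adjusted p listed at 0 for both tools in the authors' deposited table. A scaffold 13 gene (300176 to 303178) was 13.6-fold higher in B in the authors' deposited table, at 32896 against 2426. By contrast, a gene on scaffold 15 (56761 to 57496) had 70446 normalized counts in A and 5185 in B, 13.6-fold lower in B by the authors' deposited table. Another on scaffold 4 (2264111 to 2265680) was 5.11-fold lower in B, with a DESeq adjusted p of 0.0239 in the authors' deposited table. These 4 abundant genes were picked out after their values had been seen. The 5 most abundant genes took 18.1% of the summed means and none of them was called by either tool. The highest of all, on scaffold 10 (496231 to 496980), held 7.27% of the total, with 745133 in A and 696625 in B in the authors' deposited table (DESeq adjusted p = 0.992).

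The direction of the calls differed with expression level. Of the 315 called genes with a mean under 50 normalized counts, 28.9% were higher in B (exact binomial 95% interval 23.9 to 34.2). The share was 35.3% (30.4 to 40.5) for means from 50 to under 200 and 49.1% (43.8 to 54.5) from 200 to under 700. Of the 358 called genes with a mean of 700 or more, 70.1% (65.1 to 74.8) were higher in B. Calls at a mean of 200 or more comprised 423 genes higher in B and 285 higher in A, against 220 and 460 below that level (Fisher's exact test, two-sided, odds ratio 3.10, p = 8.32e-25; genes are not independent replicates). The median log2 fold change of genes with a mean above 0 in both arms, called or not, ran from -0.28 in the lowest tier to 0.28 in the highest. Setting the arm totals equal would lower every log2 value by 0.17. Among the same calls at 2-fold, the share higher in B would then run from 28.9% in the lowest tier to 65.4% in the highest. Because this shift is the same at every level, it cannot tell a strain difference from a bias that changes with level.

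**Figure D2:**
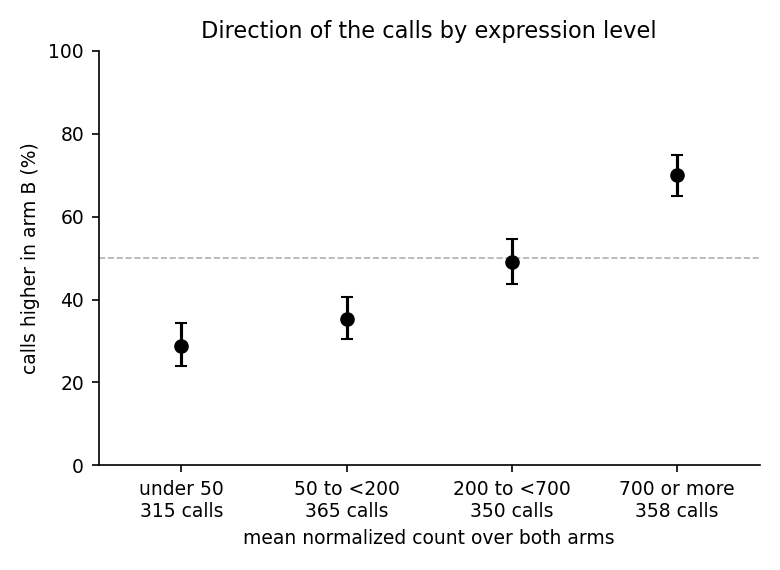
Percent of called genes that were higher in arm B (y axis) in 4 tiers of mean normalized count over both arms (x axis), with exact binomial 95% intervals as bars and the number of calls under each tier. The share rises from 28.9% under 50 to 70.1% at 700 or more, and the dashed line marks 50%.

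A gene was taken as detected in 1 arm only if it was listed at 0 in 1 arm and at 50 or more normalized counts in the other. By the authors' deposited table, 6 genes met this with A at 0 and 2 genes with B at 0. Without the minimum in the other arm, 46 genes were listed at 0 in A and 107 in B in the authors' deposited table. With at most 1 normalized count allowed in the low arm, the 8 genes became 21. Of these, 12 were low in A and 9 low in B. Such genes may be silent in the low arm, or absent or diverged in that strain, which would also leave few or no counts.

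The 2 tools behind the authors' deposited table were then compared. The edgeR columns called 1984 genes at an adjusted p under 0.05, of which 904 were higher in B and 1080 higher in A. Both tools called 1349 genes, with the same sign in every case, DESeq alone called 39 and edgeR alone 635. The genes called by edgeR alone had a median absolute log2 fold change of 1.08 in the authors' deposited table, against 1.96 for those called by both. Across the 9127 genes with a finite log2 fold change in both, Pearson's r between the tools was 0.999, a correlation across genes, which are not independent replicates.

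Genes called different lay next to each other more often than chance placement gave. Of the 9216 pairs of neighbouring genes on a scaffold, 269 were called in the same direction, against a mean of 104 and a maximum of 148 in 10000 random shuffles of the calls over the genes (one-sided permutation p = 0.0001, the smallest these shuffles can give). Neighbours called in opposite directions numbered 67, against a mean of 103 in the shuffles (one-sided permutation p for fewer = 0.0002). In all, 474 called genes sat in 205 runs of 2 or more same-direction neighbours, and 7 runs held 5 genes or more, against at most 2 such runs in 1000 shuffles. This comparison was chosen after the data had been seen.

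The longest run lay on scaffold 18, where 8 consecutive genes between 225359 and 249191 were all higher in A. For the 7 of them with more than 3 counts in B, the log2 fold changes in the authors' deposited table ran from -5.42 to -1.45. The eighth had 202 normalized counts in A and 0.760 in B in the authors' deposited table, where B was worth 2 counts, a ratio of 266 with a 95% counting interval from 73.7 to 2199. In the authors' deposited table the highest DESeq adjusted p among them was 0.0037. On the same scaffold, 5 consecutive genes between 186989 and 208898 were higher in A. In the authors' deposited table, 2 of the 5 were listed at 0 in B, at least 40.7-fold and 29.5-fold lower in B, and the 2 with more than 3 counts in B had log2 fold changes of -4.41 and -3.17. Taken from the start of one run to the end of the other, this 62.2 kb interval holds 17 genes, and all 17 had a lower mean in B. The 4 of them not called by DESeq had log2 fold changes from -1.21 to -0.84 in the authors' deposited table, where edgeR called 3 of these 4, with adjusted p from 0.024 to 0.049, and listed the other at 0.0517.

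**Figure D3:**
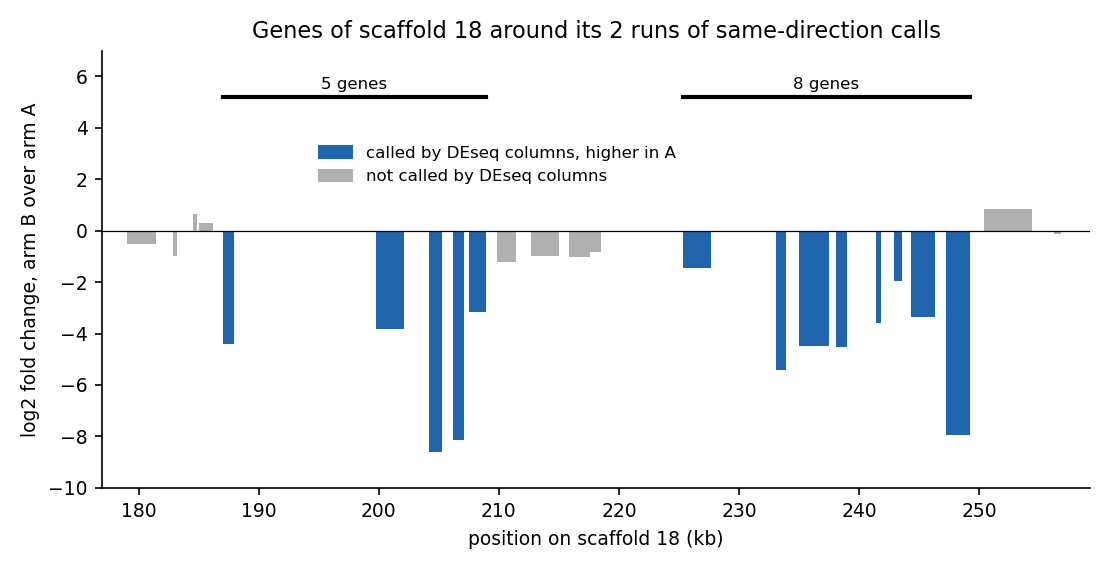
Log2 fold change of arm B over arm A (y axis, edgeR column of the authors' deposited table) for the genes of scaffold 18 around its 2 runs, with each bar as wide as its gene model (x axis, position in kb). Blue bars are genes called higher in A by the DESeq adjusted p and grey bars genes not called by it, of which edgeR called 3 of the 4 between the runs; the black lines mark the runs of 5 and 8 genes. The bars of the 2 genes listed at 0 in B, in the run of 5, show the fitted value.

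Scaffold 13 carried 2 runs of opposite direction. Between 581802 and 597580, 6 genes were higher in A. The 4 of them with more than 3 counts in B had log2 fold changes from -5.91 to -2.54 in the authors' deposited table, and 1 was listed at 0 in B, at least 34.2-fold lower. Near the start of the scaffold, between 8577 and 14934, 5 genes were higher in B. One was the gene model scaffold_13-snap.5.1, listed at 0 in A, and the other 4 had log2 fold changes from 2.01 to 9.08 in the authors' deposited table. Of the remaining runs of 5, that on scaffold 6 (1545676 to 1560570) was higher in B, and its first gene had 20161 normalized counts in B against 3993 in A in the authors' deposited table. The runs of 5 on scaffold 14 (447528 to 462936) and scaffold 16 (483335 to 499622) were higher in A. All genes of the 7 runs were also called in the same direction by edgeR, and no 2 gene models within a run overlapped.

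The share of genes called different ranged widely among the 23 scaffolds with at least 40 genes. On scaffold 18, 33 of 99 genes (33.3%, exact binomial 95% interval 24.2 to 43.5) were called, against 14.8% elsewhere (Fisher's exact test, two-sided, adjusted p = 9.38e-05). Scaffold 13 followed with 66 of 269 genes (24.5%, 19.5 to 30.1; adjusted p = 0.000207), and scaffold 11 was low with 20 of 302 (6.62%, 4.09 to 10.04; adjusted p = 9.38e-05). Fisher's exact test put 5 scaffolds above the rest and 5 below after adjustment over the 23. That test treats genes as independent, whereas called genes lay side by side. When the calls were rotated along the gene order, which keeps neighbours together, no scaffold differed from the rest after adjustment, and 2 had an unadjusted two-sided rotation permutation p under 0.05. For scaffold 18 that p was 0.00453 (adjusted p = 0.104) and for scaffold 13 it was 0.0334 (adjusted p = 0.381).

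**Figure D4:**
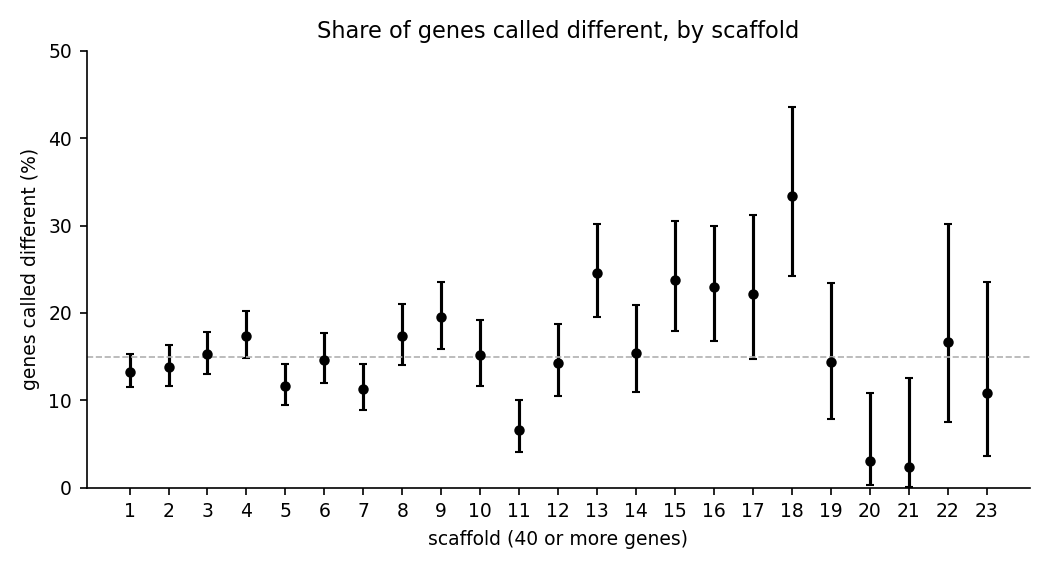
Percent of genes called different between the arms (y axis) for each of the 23 scaffolds with at least 40 genes (x axis), with exact binomial 95% intervals as bars. The dashed line marks the share over all genes, 15.0%, and scaffold 18 stands highest at 33.3%.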

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

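All tests in this part were chosen after the values they use had been seen. The comparison of the parents does not use the edgeR column of average expression, in log2 CPM, and that column carries a signal of its own. On scaffold 2 (2251128 to 2252899), a gene had 13.6 normalized counts in A and 1048 in B, yet its average in the authors' deposited table was 11.60, which is 5.82 log2 units above its level in the 6 libraries compared. In all, 26 genes with a mean of at least 100 had an average more than 2-fold above their level in those 6 libraries, with no control libraries to set beside them. Another of them, on scaffold 14 (19524 to 22003), stood at 20432 in A and 24407 in B, with an excess of 2.51 in log2 and no call by either tool in the authors' deposited table.

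The gap between a gene's mean and its average argues against an average over the 6 libraries alone, since its SD over 6148 genes with a mean of at least 100 was 0.277 in log2, where a single constant would give an SD near 0. If the average covered these 6 libraries and 6 others, a gene silent in the others would sit about 1 log2 unit above the centre at most; the highest value was 1.01, and no gene passed 1 by more than 0.05. Of the genes at least 32-fold apart, 12 of 35 (34.3%, exact binomial 95% interval 19.1 to 52.2) lay at 0.8 or more. Of the genes that differed by under 0.5 in log2, 0 of 3447 did (Fisher's exact test, two-sided, p = 1.28e-25). This contrast cannot decide whether the other set was the same 2 strains at another time. The 35 genes were chosen for their difference at the time compared. A gene silent in both strains at another time would also lie at 0.8 or more. Candidate explanations are that the average also covers 6 libraries of other strains, such as the progeny, or of these strains at another time. Which libraries these were is open.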

How the results depend on the processing

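No paired analysis was possible because the authors' deposited table holds 1 mean per arm and carries no replicate numbers. For the same reason, DESeq2, other normalizations (RLE, upper quartile, total counts), no filter on low counts, leaving out replicates and pseudocounts were not run; list tests were not run because no list entry matched. Overlapping models, equal totals, shares of direction, neighbour and scaffold settings were chosen after seeing the data. At an adjusted p under 0.01 the calls fell to 891 (also 891 at 2-fold, and 855 by both tools), because the limit is stricter. With a mean of at least 10 CPM they fell to 909 (908 at 2-fold), because genes below that level were left out. The share higher in B then rose from 46.3% to 54.6%, so that the majority changed sides. With equal arm totals and a 2-fold limit after the shift, 43.3% were higher in B. A 4-fold limit left 659 genes. With a floor of 3 counts before rescaling, also chosen after seeing the data, the bounds of 326-fold and 139-fold fell to 196-fold and 83.7-fold. Genes detected in 1 arm only numbered 21 with at most 1 normalized count in the low arm, 41 with 1 CPM in the other arm and 0 with 50. By rotation 0 of 23 scaffolds stood apart, against 10 by Fisher's exact test. The excess of same-direction neighbours kept its direction and its side of the threshold under all 7 alternatives, from 2.21 times chance with the edgeR columns to 3.37 at an adjusted p under 0.01. With 1 mean per arm, depth cannot be set against the spread between libraries.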

Other observations

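The tests in this part were chosen after the values they use had been seen. Same-direction calls among neighbours did not depend detectably on gene orientation: 3.01% of 2494 divergent pairs, 2.52% of 2501 convergent pairs and 3.10% of 4221 pairs on the same strand were called in the same direction (Fisher's exact test, two-sided, divergent against convergent p = 0.301, same against different strand p = 0.352). Pairs farther apart were compared with shuffles of single calls over all genes. Such shuffles break up the runs of neighbours and the differences between scaffolds, so they cannot show whether the excess reached past these. Genes 2 places apart were called in the same direction 172 times against 103 in shuffles, and genes 10 places apart 126 times against 99.8 (one-sided permutation p = 0.001 and 0.005, adjusted over 4 distances 0.004 and 0.01), whereas at 20 places the count was 97 against 97.6 (p = 0.54). The 40 scaffolds with under 20 genes held 164 genes, of which 7 (4.27%) were called, against 15.0% of all genes.

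If the average level covers 6 other libraries, their mean can be placed between arm A (0) and arm B (1) for each called gene at least 4-fold apart. Of 486 such genes with a mean of at least 20, 165 lay under 0.25, 178 between 0.25 and 0.75 and 143 above 0.75. Each direction leaned toward the arm where the gene was low. The median position was 0.263 for genes higher in B and 0.633 for genes higher in A. Because these genes were chosen for their difference in the libraries compared, that choice alone may give such a lean. Pairs of these genes 20 to 200 kb apart had similar positions (Spearman rho = 0.293 over 1445 pairs, one-sided permutation p = 0.0001, the smallest the permutations can give), which is consistent with the hypothesis that neighbouring genes took their level from 1 parent in the other libraries, as alleles inherited together would. Pairs called in opposite directions within 200 kb, which co-regulated clusters alone were assumed to leave unrelated, gave a rho of 0.196 over 702 pairs. The mean in permutations within each direction was -0.070 (one-sided permutation p = 0.0001). These permutations shuffle single genes, so they do not show what clusters alone would give. The rho was also under the 0.2 set for excluding clusters, so co-regulation stays open. The identity of the other libraries was not tested directly.

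Some whole numbers never occurred in the counts behind the low means. In 1 library of arm A no low mean used a count of 1 or 4, while 143 genes had a count of 2 and 84 a count of 3, and in 1 library of arm B none used a count of 2, while 171 genes had 1 and 80 had 3. The numbers held by at least 5 genes in these 2 libraries arise if whole counts were multiplied by a factor from 1.5 to 1.749 and from 1.25 to 1.299 and rounded, so rescaling to whole numbers before the test may be the source. Read pairs counted as 2 reads are argued against, since at least 44.2% of the nonzero counts of these libraries were odd. No biological explanation was tested for this pattern. If the counts were rescaled in this way, both tools took enlarged numbers as reads. Their p-values may then understate counting error in these 2 libraries, and the effect on the calls was not tested.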
